A study of Mus musculus with 38 samples.

How the data were processed

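Peak lists of H3K27ac, c-Fos, FosB and JunB ChIP-seq from cultured mouse cortical neurons were analysed as the authors deposited them. Reads were aligned with BWA to genome build mm9, per the submitters' processing notes, which give no version. The peak names begin with the name of the peak caller MACS, per the deposited files, and its version and the control library it used are not given in the sources used here. Each AP-1 list was called by the authors on 1 library. The H3K27ac lists were called on biological samples 1 and 2 merged, per the labels, for the whole genome and for distal peaks, and every distal peak was found with the same coordinates in the list for the whole genome. The score of a peak in the deposited lists rises with the negative log10 of its p-value on the scale of MACS, and the lowest score in the AP-1 lists was 50, which stands for 1e-05. Scores were used to rank and filter peaks within a list. Other deposited lists give single positions: the authors' combined c-Fos sites, 11830 distal sites with CBP and H3K4me1, and the 4 classes of these sites by H3K27ac. How the combined sites and the classes were made is not given in the sources used here. The classes were checked against the H3K27ac lists: constant sites lay in peaks of both conditions in 100% of cases, increasing sites in 27.9% without stimulation and 100% after KCl, decreasing sites in 100% and 33.6%, and sites with no H3K27ac in neither.

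Groups and biological sample numbers were taken from the labels. Libraries with the same number share a biological sample, per the labels, and the numbers deviated together: biological sample 3 had more peaks than 4 in 6 of 6 groups, and 5 more than 6 in 4 of 4. Peaks overlapped when they shared at least 1 bp. The difference in mean log2 peak number was tested with an exact permutation test of the library labels. Overlap by chance was measured with 100 rotations of the peaks within each chromosome, whose length was taken as the farthest peak end, and with 20 rotations for the enhancer classes. Shares of sites were compared with Fisher's exact test, two-sided, with odds ratios, Woolf 95% intervals and Benjamini-Hochberg adjustment. Shares carry Wilson 95% intervals that cover counting error only, since sites are not replicate cultures. The depth of every library is unknown because the lists hold no read counts. It had been planned to count an enhancer as occupied when a combined c-Fos peak overlapped it, but the combined list turned out to hold positions without width. A combined site within 500 bp of the enhancer was used instead, chosen after the format of the list was seen. Single libraries kept the planned rule, with the enhancer inside a peak. Non-distal H3K27ac peaks are those of the list for the whole genome that are not in the distal list.

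The sites named were chosen by a rule set in advance: the 5 increasing enhancers and 5 combined c-Fos sites overlapped by c-Fos peaks in the most of 6 KCl c-Fos libraries (control shRNA included), ties by the mean rank of the overlapping peak's score within its list. The settings varied, as fixed before the data were examined, were a score of at least 100 (which stands for 1e-10), other overlap rules (50% of the shorter peak, centres within 200 bp), lists of the same length, autosomes only, peaks within 500 bp merged, other c-Fos lists, c-Fos within 200 bp or 1 kb of an enhancer, FosB or JunB in place of c-Fos, each biological sample left out, and the replicate block. Distances to transcription start sites, gene assignment and DNA motifs were not analysed here, because no genome or annotation of build mm9 was used. Input DNA was not analysed here. The overlap and odds ratio steps were tested on simulated data: 100% of planted overlaps among 23578 control shRNA c-Fos peaks of biological sample 5 were found and 0% of the others called. For increasing against constant enhancers with a simulated odds ratio of 3, 96% of 500 intervals held the true value and 100% were called, and 4% were called without a difference. The simulated sites were drawn independently, and the planted peaks lay near peak centres. These simulations therefore checked the code and not the effect of sites that lie close together or share cultures. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.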

Results

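The study mapped the activity of distal enhancers in cultured mouse cortical neurons before and after depolarisation, by chromatin immunoprecipitation followed by sequencing (ChIP-seq). The neurons came from C57BL/6 embryos of day 16.5 and were used after 7 days in vitro. They had been silenced overnight with TTX (1 µM), a sodium channel blocker, and DL-AP5 (100 µM), an NMDA receptor antagonist. They were then left silenced (unstimulated) or depolarised with KCl for 2 h. Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped in biological samples 1 and 2. The AP-1 proteins c-Fos, FosB and JunB, which activity induces in neurons and which bind DNA as Fos-Jun pairs, were mapped in biological samples 3 to 6. c-Fos was mapped with the antibodies sc52 and sc7202, FosB with sc48 and JunB with sc46. Biological samples 5 and 6 were infected with a control shRNA or an shRNA against c-Fos or FosB and were all given KCl.

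Of the 38 samples, 22 were AP-1 libraries, 4 were H3K27ac libraries and 12 were input DNA, which has no peak list and is not analysed here. Each AP-1 group had 2 libraries, 1 per biological sample, except JunB, which had 1 library per condition, from biological sample 4. The AP-1 peak lists held between 557 and 28885 peaks. The sequencing depth behind them is unknown, because the files hold peaks and not reads, so a difference in list length includes any difference in depth. The H3K27ac lists merge biological samples 1 and 2 and have no replicates. Positions are those of genome build mm9.

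Depolarisation was followed by a large increase in the number of c-Fos peaks. The 4 unstimulated lists held 1972 ± 1282 c-Fos peaks (SD, n = 4 libraries) and the 4 KCl lists held 18583 ± 9389 (SD, n = 4). With sc52, the list grew from 3669 to 22368 peaks in biological sample 3 (6.10-fold) and from 1891 to 6808 in biological sample 4 (3.60-fold). With sc7202, it grew from 1770 to 28885 peaks (16.3-fold) and from 557 to 16270 peaks (29.2-fold). Many of the peaks listed in silenced neurons were also listed after KCl: 76.7% and 67.2% of the unstimulated sc52 peaks and 47.3% and 57.8% of the unstimulated sc7202 peaks overlapped a KCl peak of the same antibody and biological sample (3 and 4). In the other direction the shares were 12.6% and 18.7% of the KCl sc52 peaks and 2.87% and 1.41% of the KCl sc7202 peaks, which the short unstimulated lists keep low. The difference in mean log2 peak number was 3.34 (exact two-sided permutation test over the 70 splits, p = 0.0286, n = 4 against 4), the smallest p that this design allows. The 4 libraries of a condition came from 2 cultures. With the biological sample and antibody as a block, the paired difference was also 3.34 and the exact sign-flip test gave p = 0.125, the smallest value that 4 pairs allow, so the call at 0.05 was lost. The difference was 2.23 with sc52 alone and 4.45 with sc7202 alone. In an alternative added after the results were seen, it was 4.05 for peaks outside the non-distal H3K27ac peaks of their condition (exact permutation p = 0.0286). Of the unstimulated sc52 peaks of biological sample 4, 1226 (64.8%) were also in the unstimulated sc52 list of biological sample 3 and in both lists under c-Fos shRNA, and 6 of them held a site of the authors' combined c-Fos list.

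FosB and JunB lists were also longer after KCl in each of the 3 pairs mapped. FosB lists held 4229 and 2041 peaks in silenced neurons and 10898 and 4899 after KCl, ratios of 2.58 and 2.40 in biological samples 3 and 4. The single JunB pair held 3126 and 19346 peaks, a ratio of 6.19. Of the unstimulated peaks, 54.0% for JunB and 37.7% and 33.5% for FosB overlapped a KCl peak of the same protein and biological sample. For FosB the difference in mean log2 peak number was 1.31 (exact two-sided permutation test, p = 0.33, n = 2 against 2, the smallest p possible), and JunB had no replicate check. The FosB and unstimulated JunB lists had narrow peaks, with medians of 176 to 254 bp in 8 of these 9 lists, against 603 to 841 bp in the KCl c-Fos lists. The exception was FosB with control shRNA in biological sample 5, at 767 bp. The KCl JunB list had a median of 680 bp, against 226 bp in its unstimulated partner. The unstimulated sc7202 list of biological sample 4, the baseline of the 29.2-fold ratio above, had the narrowest peaks of all lists, with a median of 157 bp against 733 bp in its KCl partner.

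**Figure D1:**
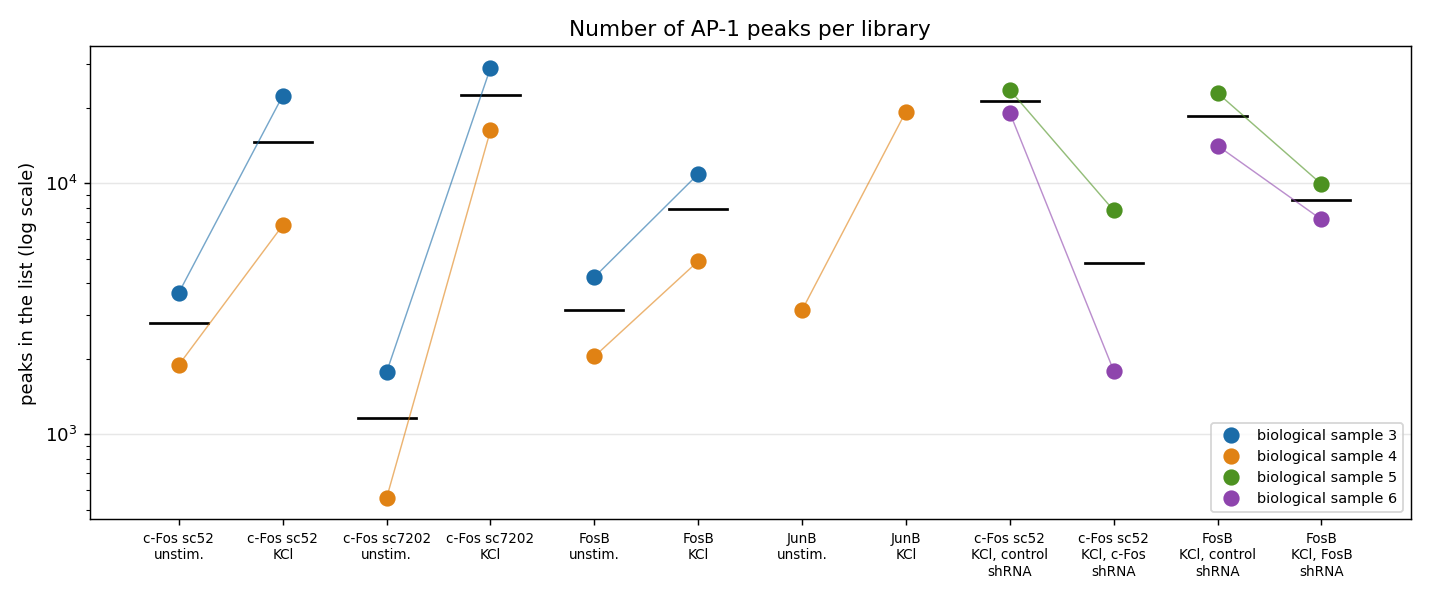
Number of peaks in each of the 22 AP-1 libraries, on a log axis, by antibody, stimulation and shRNA. Each point is 1 library, coloured by biological sample, thin lines join libraries of the same biological sample, and the black bars are the group means. Every KCl list without shRNA was longer than its unstimulated partner, and every list under shRNA against the protein mapped was shorter than its control shRNA partner.

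The shRNA libraries compared peak lists with and without shRNA against the protein mapped. The level of the protein left was not measured here, and list length includes any difference in depth. Under c-Fos shRNA the sc52 list held 7808 peaks in biological sample 5, against 23578 with control shRNA (66.9% fewer), and 1793 against 19131 in biological sample 6 (90.6% fewer). Of the c-Fos peaks seen with control shRNA, 22.5% and 5.45% were found under c-Fos shRNA, a mean of 14.0% ± 12.1 (SD, n = 2 biological samples). Between the control shRNA lists of biological samples 5 and 6, a single pair, the corresponding shares were 52.3% and 64.6% in the 2 directions (mean 58.4%). The peaks that stayed were unevenly placed. In biological sample 5, 64.9% of control peaks inside non-distal H3K27ac peaks were found under c-Fos shRNA, against 21.2% inside distal H3K27ac peaks and 5.99% outside H3K27ac. In biological sample 6 these shares were 49.6%, 3.11% and 1.23%. The difference in mean log2 peak number between c-Fos shRNA and control shRNA was -2.50 (exact two-sided permutation test, p = 0.33, n = 2 against 2, the smallest possible). Counted outside non-distal H3K27ac peaks it was -4.08. With control and knockdown lists cut to the same number of best-scoring peaks, 31.97% ± 10.3 (SD, n = 2) of the control peaks were found under c-Fos shRNA. In the other control list 56.8% and 55.5% were found, from the single control pair read in both directions.

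FosB lists were also shorter under FosB shRNA in both biological samples. The sc48 list held 9941 peaks against 22933 with control shRNA in biological sample 5 (56.7% fewer) and 7180 against 14139 in biological sample 6 (49.2% fewer). Median peak widths were 221 bp against 767 bp in biological sample 5 and 234 bp against 254 bp in biological sample 6. FosB shRNA left 27.9% and 30.1% of the control FosB peaks, a mean of 29.0% ± 1.53 (SD, n = 2). Between the control lists, a single pair, the shares were 38.0% and 64.6% in the 2 directions (mean 51.3%). The difference in mean log2 peak number was -1.09 (exact two-sided permutation test, p = 0.33, n = 2 against 2, the smallest possible). With lists cut to the same number of best-scoring peaks, 46.3% ± 1.06 (SD, n = 2) were found under FosB shRNA. In the other control list 51.8% and 54.0% were found, from the single control pair read in both directions. The cut acts on list length, which itself differed with FosB shRNA. By place, 24.4% and 29.2% of control FosB peaks inside non-distal H3K27ac peaks were found under FosB shRNA in biological samples 5 and 6, against 41.8% and 38.1% inside distal ones and 24.0% and 27.8% outside H3K27ac. Whether c-Fos and FosB differed was not tested.

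c-Fos was mapped to many of the same sites in different cultures and with different antibodies. Over the 15 pairs of the 6 KCl c-Fos lists, 57.3% to 82.6% of the peaks of the shorter list overlapped the longer one, with a mean of 71.8%. A longer list raises this share: with lists cut to the same number of best-scoring peaks it was 49.7% to 67.5%, with a mean of 58.4%. All other shares in this paragraph use the full lists. The mean was 73.7% ± 10.04 (SD, 7 pairs) between biological samples with the same antibody and 72.8% ± 0.71 (SD, 2 pairs) between antibodies in the same biological sample. Rotating the peaks along their chromosomes gave at most 2.14% in any of 100 rotations of a pair. Of the 12594 c-Fos sites that the authors combined from several libraries, 99.2% lay in at least 2 of the 4 KCl sc52 lists, 91.2% in at least 1 KCl sc7202 list and 24.3% in all 6 lists. The rule that made this list is not given in the sources used here and may have used the KCl sc52 libraries. These shares may therefore be set by the rule and are not a measure of agreement between cultures. At least 1 of the 4 unstimulated c-Fos lists held 1.21% of the combined sites. This was a smaller share than the 12.6% and 18.7% of KCl sc52 peaks given above for single libraries. The c-Fos shRNA lists of biological samples 5 and 6 held 5.09% and 0.437%. These shares too may be set by the rule and do not measure binding without stimulation or under c-Fos shRNA. The 4 KCl sc52 lists held 65.8% to 99.6% of the 1226 sc52 peaks described above, yet 6 of these peaks held a combined site.

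FosB and JunB occupied many of the same sites as c-Fos. Of the FosB peaks found after KCl, 78.7% and 51.0% overlapped a c-Fos sc52 peak of the same biological sample (3 and 4), as did 63.1% and 70.5% with control shRNA (5 and 6). The mean with sc52 was 65.8% ± 11.8 (SD, n = 4), and rotated peaks gave at most 1.79%. With sc7202 the shares were 70.2% and 71.0% in biological samples 3 and 4, so the difference between these cultures was seen with sc52 alone. JunB peaks overlapped the sc52 list of biological sample 4 in 26.3% of cases and its sc7202 list in 55.9%, against at most 1.15% for rotated peaks. The sc52 list was the shorter, and 74.4% of its peaks overlapped a JunB peak. With lists of the same length 54.6% of JunB peaks were shared. In the other direction, 35.1% and 34.2% of the sc52 peaks of biological samples 3 and 4, and 61.1% and 49.7% of those with control shRNA, overlapped a FosB peak. In biological sample 4, 81.7% of the 4899 FosB peaks overlapped a JunB peak, and 19.7% of the 19346 JunB peaks overlapped a FosB peak.

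The 4 enhancer classes of the authors tested whether AP-1 binding went with the change in acetylation. The classes were drawn from 11830 distal sites marked by CBP, a histone acetyltransferase, and by H3K4me1, a mark of enhancers, and they hold 1468 sites with increasing, 800 with constant, 738 with decreasing and 1886 with no H3K27ac. c-Fos was most frequent where H3K27ac increased. A combined c-Fos site lay within 500 bp of 42.3% of increasing enhancers (Wilson 95% interval 39.8 to 44.8%), 30.1% of those with no H3K27ac (28.1 to 32.2%), 17.1% of constant ones (14.7 to 19.9%) and 11.1% of decreasing ones (9.04 to 13.6%). With the c-Fos sites rotated along the chromosomes, the highest share in any class was 1.08%. The odds ratio of increasing enhancers was 5.87 against decreasing ones (95% interval 4.56 to 7.55, Fisher's exact test, two-sided, p = 2.69e-55, Benjamini-Hochberg adjusted over 3 comparisons p = 8.06e-55). It was 3.55 against constant ones (2.87 to 4.38, Fisher's exact p = 5.87e-36, adjusted p = 8.81e-36) and 1.70 against those with no H3K27ac (1.47 to 1.96, Fisher's exact p = 3.13e-13, adjusted p = 3.13e-13). Sites were the units of these tests and are not independent cultures. The ratio against sites with no H3K27ac rose to 2.79 with c-Fos peaks shared by all 4 KCl libraries without shRNA, and the ratio against decreasing sites was 2.94 with JunB in place of c-Fos.

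The same order held in single libraries. A c-Fos peak covered 52.1% ± 13.4 of increasing enhancers (SD, n = 6 KCl libraries from 4 cultures), 34.05% ± 11.4 of those with no H3K27ac, 24.5% ± 9.03 of constant and 19.3% ± 8.20 of decreasing enhancers, and the order of the 4 classes was the same in 6 of 6 libraries. In silenced neurons the 4 c-Fos libraries covered 0.255% ± 0.340 of increasing enhancers (SD, n = 4). FosB covered 33.8% ± 17.9 of increasing and 17.3% ± 12.3 of constant enhancers (SD, n = 4), and the single JunB library covered 57.6% and 30.5%. With c-Fos shRNA, coverage of increasing enhancers was 11.2% in biological sample 5 and 0.272% in biological sample 6, against 53.8% and 52.9% with control shRNA. The other classes were also lower in both. Their means were 2.55% against 37.0% with no H3K27ac, 3.5% against 23.8% for constant and 2.64% against 17.7% for decreasing enhancers. FosB coverage of increasing enhancers was 26.8% and 18.5% with FosB shRNA, against 56.9% and 38.3% with control shRNA. It was lower in the other classes too, with means of 16.7% against 34.7% with no H3K27ac and 15.75% against 25.6% for constant enhancers. Whether the classes differed in these losses was not tested. In biological sample 5 the control FosB peaks were wider (median 767 against 221 bp), and a FosB peak centre lay within 200 bp of 30.6% of increasing enhancers with FosB shRNA and 49.2% with control shRNA (20.6% and 40.6% in biological sample 6). All 6 KCl c-Fos lists held a peak at 334 of the 1468 increasing enhancers (22.8%) and at 59 of the 800 constant ones (7.38%), while 333 increasing (22.7%) and 430 constant enhancers (53.8%) had none in any list.

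**Figure D2:**
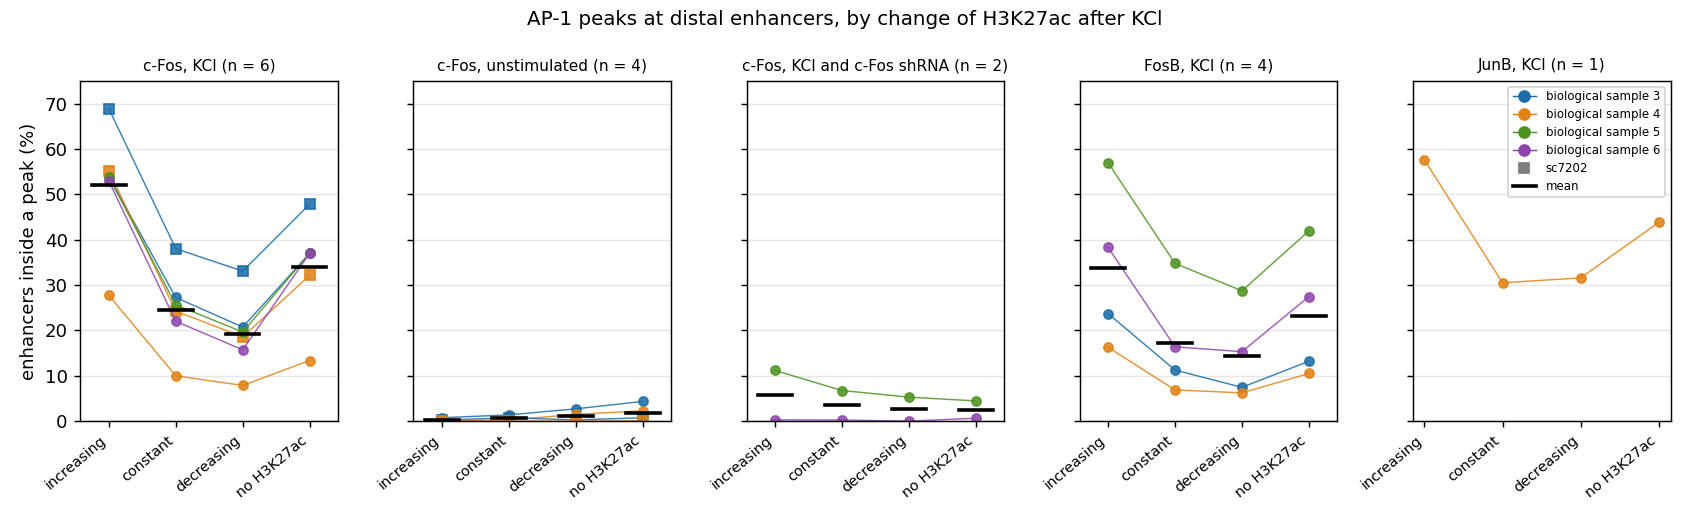
Share of the enhancers of each H3K27ac class that lay inside an AP-1 peak, in percent, for single libraries. Points are libraries, coloured by biological sample and square for sc7202, lines join the classes of 1 library, and black bars are means over libraries. In the 6 KCl c-Fos libraries the increasing class has a mean of 52.1% and the decreasing class 19.3%, and in the 4 unstimulated c-Fos libraries no class exceeds 4.35%.

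The 5 increasing enhancers with the best-ranked c-Fos peaks in all 6 KCl libraries were named by position alone, with no gene assigned. They lay at position 70822380 of chromosome 6, 50999465 of chromosome 3, 93892340 of chromosome 2, 19735515 of chromosome 11 and 59312325 of chromosome 15. None held a c-Fos peak in any unstimulated library, and each lay in all 4 KCl FosB lists and in the KCl JunB list. Under c-Fos shRNA the site on chromosome 3 kept a peak in both libraries and the other sites in 1. On chromosome 6 the H3K27ac peak after KCl reached from 70820822 to 70824011 (the authors' score 243.53) and no unstimulated peak was listed. The site on chromosome 15 was the only member of the 5 with a peak in both conditions, from 59310814 to 59313748 after KCl (score 1026.35) and from 59311181 to 59312830 without stimulation (score 72.98). The scores describe each list on its own and are not a measure of change.

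The 5 best-ranked sites of the combined c-Fos list lay at position 66311213 of chromosome 17, 45719410 and 58755968 of chromosome 13, 95107193 of chromosome 15 and 107389461 of chromosome 1. In the c-Fos list of biological sample 5 with control shRNA, the peak on chromosome 17 reached from 66310473 to 66311880. None of the 5 lay in an H3K27ac peak of either condition. All 5 lay in the 4 KCl FosB lists and the KCl JunB list, and each kept a peak in at least 1 c-Fos shRNA library. The site on chromosome 1 was also bound in 2 unstimulated c-Fos libraries.

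The H3K27ac lists of silenced and KCl-treated neurons were of similar length but held partly different peaks. The distal lists held 19628 peaks in silenced neurons and 18556 after KCl. Of the KCl peaks, 4902 (26.4%, Wilson 95% interval 25.8 to 27.1%) overlapped no unstimulated peak, and of the unstimulated peaks 5975 (30.4%, 29.8 to 31.1%) overlapped no KCl peak. Over the whole genome the lists held 30239 and 29418 peaks, with 5329 (18.1%) present after KCl alone and 6105 (20.2%) in silenced neurons alone. Peaks found in a single condition were narrower, with medians of 1840 bp for KCl and 1776 bp for unstimulated distal peaks, against 2394 bp for the KCl peaks found in both. Each list merges 2 biological samples, so no replicate error can be given, and a peak that crossed the threshold counts as gained or lost.

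By share of peaks, a c-Fos site was most frequent in the distal H3K27ac peaks that were present after KCl alone. A combined c-Fos site lay in 978 of these 4902 peaks (19.95%, Wilson 95% interval 18.9 to 21.1%), in 10.9% (10.4 to 11.5%) of the 13654 peaks present in both conditions and in 3.83% (3.37 to 4.35%) of the 5975 peaks present in silenced neurons alone. The odds ratio of KCl-alone against shared peaks was 2.03 (95% interval 1.86 to 2.22, Fisher's exact test, two-sided, p = 2.78e-53, adjusted over 6 comparisons p = 3.34e-53). Against peaks of silenced neurons alone it was 6.25 (5.39 to 7.26, Fisher's exact p = 9.64e-163, adjusted p = 5.79e-162). The direction was the same in 6 of 6 KCl c-Fos libraries. In sc52 libraries of biological samples 3 and 4, 25.5% and 13.3% of KCl-alone peaks held a c-Fos peak, against 20.9% and 7.40% of shared peaks. Compared within 10 strata of peak width, the odds ratio was 3.44 (3.10 to 3.81).

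**Figure D3:**
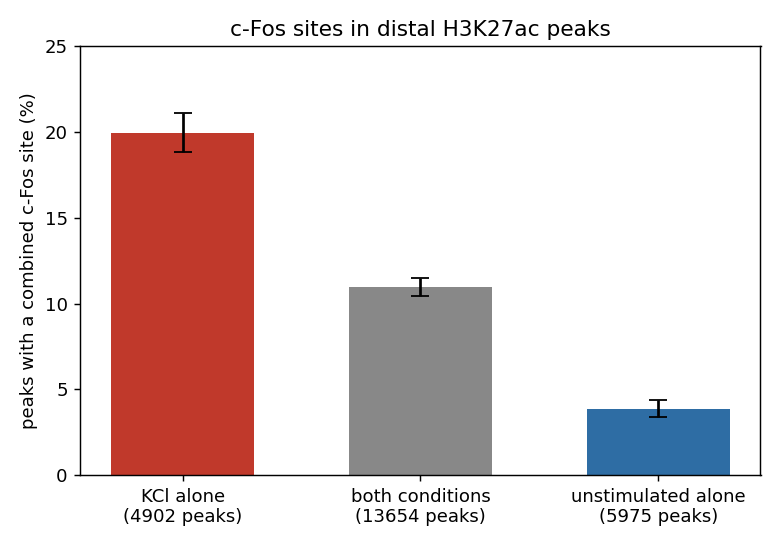
Share of distal H3K27ac peaks that hold a site of the combined c-Fos list, in percent, for peaks present after KCl alone, in both conditions (KCl list) and in silenced neurons alone. Bars are shares of peaks and error bars are Wilson 95% intervals, which cover counting error only; the shares are 19.95%, 10.9% and 3.83%.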

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

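The test reported here was chosen after the data were seen. c-Fos peaks were also present at distal CBP and H3K4me1 sites that the authors placed in no H3K27ac class, which no comparison above used. Of these 6938 sites, 31.6% ± 10.7 (SD, n = 6 KCl libraries, range 13.1 to 46.2%) lay in a c-Fos peak, above the highest value in the 4 unstimulated c-Fos libraries, 1.77%. The unstimulated lists were much shorter, and every H3K27ac class met the same rule, so this is not particular to these sites. Decreasing enhancers, for example, had 7.86 to 33.1% after KCl against at most 2.71%. A combined c-Fos site lay within 500 bp of 24.5% of them (Wilson 95% interval 23.5 to 25.5%), which is above the constant class and below the class with no H3K27ac. No group had the 4 or more samples that a check for libraries far from the others needs, the largest having 3.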

How the results depend on the processing

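Alternatives chosen after the data were seen were counts without peaks in non-distal H3K27ac peaks, enhancers thinned to over 2 kb apart, FosB coverage by peak centres and strata of H3K27ac peak width. Of 103 values under all alternatives none reversed. The overlap shares and the shares of H3K27ac peaks gained and lost have no direction, so they could not reverse. All 9 alternatives of each of the 3 enhancer odds ratios and all 5 of the H3K27ac odds ratio stayed past the threshold (3.09 to 3.77 against constant, 2.94 to 6.99 against decreasing, 1.42 to 2.79 against no H3K27ac, 1.99 to 3.44 for H3K27ac). For c-Fos after KCl, the log2 difference in peak number kept its direction but not its call with fewer libraries: 3.32 to 3.36 without a biological sample, 2.23 with sc52 alone and 4.45 with sc7202 alone (exact permutation p = 0.33, n = 2 against 2, the smallest possible). In the paired analysis by block it was 3.34 (exact sign-flip p = 0.125); the paired log2 differences of 1.31 for FosB after KCl, -2.50 under c-Fos shRNA and -1.09 under FosB shRNA rest on 2 pairs, which cannot reach 0.05, so no other call could change. Without peaks in non-distal H3K27ac peaks the change under c-Fos shRNA was -4.08. Leaving out a biological sample gave -3.42 to -1.59 under c-Fos shRNA. With lists of the same length, the share of control peaks found rose to 31.97% under c-Fos shRNA and 46.3% under FosB shRNA, c-Fos overlap between libraries fell to 58.4%, JunB overlap with c-Fos rose to 54.6%, and H3K27ac peaks gained and lost were 28.5% and 28.5%. With centres within 200 bp, the FosB shRNA share was 27.3% and JunB overlap 24.8%. With scores of at least 100, JunB overlap was 18.2%. Over the whole genome, 18.1% of H3K27ac peaks were gained and 20.2% lost. Lists of the same length compare fewer, better-scoring peaks, and the cause of the changes listed here was not tested. Alternatives for start-site distance, motifs and gene lists were not run, since no mm9 reference was used. Depth, which the lists do not give, limits every peak number.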

Other observations

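All tests in this part were chosen after the results they bear on were seen. In silenced neurons FosB and JunB covered a larger share of enhancers with no H3K27ac than of increasing ones, unlike after KCl, when the increasing class led. The unstimulated JunB list of biological sample 4 covered 11.03% of enhancers with no H3K27ac (208 of 1886, Wilson 95% interval 9.69 to 12.5%), 4.47% of decreasing, 3.50% of constant and 1.98% of increasing enhancers (1.38 to 2.82%). The odds ratio of sites with no H3K27ac against increasing sites was 6.15 (95% interval 4.14 to 9.13, Fisher's exact p = 3.33e-27, adjusted over 7 libraries p = 2.33e-26). It was 4.09 (2.49 to 6.72) and 7.06 (1.64 to 30.5) for unstimulated FosB in biological samples 4 and 3 (adjusted Fisher's exact p = 6.27e-10 and 0.00324). The ratio in biological sample 3 rests on 18 of 1886 sites with no H3K27ac and 2 of 1468 increasing sites. In biological sample 4 FosB covered 5.09% of sites with no H3K27ac (4.19 to 6.18%) and 4.34% of decreasing ones (3.09 to 6.06%), whose intervals overlap, 3.25% of constant and 1.29% of increasing ones. Among the unstimulated c-Fos lists, both sc52 lists passed the same test. Their odds ratios were 6.02 (3.20 to 11.3) and 34.2 (4.71 to 249) in biological samples 3 and 4, and the latter list covered 0.0681% of increasing sites. Neither sc7202 list passed (adjusted Fisher's exact p = 0.0543 and 0.508). The sc7202 lists covered at most 0.742% of the sites with no H3K27ac or of increasing ones, too few to compare the antibodies. Of the 208 sites with unstimulated JunB and no H3K27ac, 81.3% were in the KCl JunB list, against 39.2% of the other sites of this class. Both JunB lists came from the same antibody and culture. The other KCl lists were uneven: in biological sample 4 the shares were 27.9% against 11.6% with sc52, 36.1% against 31.6% with sc7202 and 25.96% against 8.58% for FosB, in biological sample 3 they were 47.6% against 35.6%, 48.1% against 47.8% and 19.7% against 12.4%, and c-Fos with control shRNA gave 38.9% against 36.8% and 37.5% against 36.9% (5 and 6). In biological sample 4, 28.5% of unstimulated JunB peaks overlapped an unstimulated FosB peak.

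The authors' combined c-Fos sites lay mostly outside the H3K27ac peaks. Of the 12594 combined sites, 72.9% lay in no H3K27ac peak of either condition, 15.5% in peaks of both, 9.46% (1191 sites) in peaks after KCl alone and 2.13% (268 sites) in peaks of silenced neurons alone. After KCl 24.9% lay in an H3K27ac peak of any kind, against at most 3.72% of rotated sites. The share was higher in each of the 6 single KCl c-Fos lists, from 27.5% to 47.9% of peaks. It was 26.5% to 47.2% of their peak centres, which have no width, as in the combined list. Distal H3K27ac peaks after KCl held similar shares: 20.3% of combined sites and 18.7% to 24.9% of the peaks of single lists. The gap lay in non-distal peaks, which held 7.97% to 27.97% of the peaks of single lists and the rest of the 24.9% of combined sites. The 72.9% may therefore be set by the rule that made the combined list, which is not given, and is not a measure of c-Fos binding in single libraries.

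A set of sc52 peaks was present with and without stimulation and under c-Fos shRNA. Of the unstimulated sc52 peaks of biological sample 4, 1226 (64.8%) were also in the unstimulated sc52 list of biological sample 3 and in both c-Fos shRNA lists; 83.5% lay in non-distal H3K27ac peaks and 6 held a combined c-Fos site. Reads gathering there whatever the antibody were argued against in biological sample 4 alone, where the 6 lists of other antibodies held at most 11.7% of them. The FosB lists with FosB shRNA and control shRNA held 17.8% and 39.7% in biological sample 5, and 7.91% and 7.01% in 6. For c-Fos remaining at its strongest sites, sc7202 in biological sample 4 found 13.2% of the KCl sc52 peaks there against 94.8% of induced peaks of the same rank. That comparison cannot decide, because the induced peaks were not matched for place. Of this sc7202 list, 8.19% lay in non-distal H3K27ac peaks. In biological sample 3 neither could be excluded, with up to 46.8% in lists of other antibodies and 47.4% found with sc7202 against 95.4%. Whether sc52 recovered chromatin with something other than c-Fos stays open: the 4 other sc52 lists held 65.8% to 99.6% of the peaks, but these were chosen with sc52 in the same cultures, so that test decides nothing.

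Peaks in non-distal H3K27ac peaks took a larger share in biological samples 3 and 5 than in 4 and 6, in 8 of 10 groups, for example 44.1% against 4.86% for FosB after KCl. Longer lists that reach weaker peaks were argued against: with lists of the same length the median difference was 14.6 percentage points, against 14.0 with all peaks, and the direction held in 10 of 10 groups. A difference between cultures or between their preparation stays open and was not tested.

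c-Fos was more frequent at enhancers with no H3K27ac than at constant ones (odds ratio 2.09, 95% interval 1.69 to 2.57, Fisher's exact p = 7.31e-13, adjusted over 3 comparisons p = 1.10e-12). The making of the combined list does not account for all of it, since the lowest odds ratio in any of the 6 KCl c-Fos libraries was 1.39 (1.06 to 1.81). c-Fos sites farther from the centre of constant enhancers may account for part but not all of it, since the odds ratio fell from 2.65 within 200 bp to 1.73 (1.42 to 2.10) within 2 kb. Weak peaks near the threshold may contribute: with scores of at least 100 the odds ratio was above 1 in 6 of 6 libraries, but 4 intervals excluded 1 and the lowest ratio was 1.10 (0.861 to 1.42). H3K27ac below the authors' threshold at these sites was not tested, nor was a biological explanation.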
